A study of Saccharomyces cerevisiae BY4741 with 6 samples.

How the data were processed

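The study holds 6 NET-seq libraries of budding yeast BY4741 with a FLAG tag on Rpb3, 1 each of the wild type and the SPP1 deletion in glucose medium and at 15 and 60 min after transfer to galactose medium. Per the labels, the galactose cultures were centrifuged and resuspended before incubation, which the glucose cultures are not described to have been. RNA that co-purified with the polymerase was sequenced.

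The values are whole-number read counts per gene, used as deposited; the submitters' processing notes name alignment with Bowtie to sacCer3, with no version given. The counting tool, the strand setting, the gene windows and the annotation are not given in the sources used here. Treatment of duplicates and of reads shared by similar genes is likewise not given, so that values of paralogs and of genes that share a span with another gene are uncertain. The table has 5219 genes, of which 5116 identifiers were found in a reference table of gene names and coordinates of the same assembly and 103 were not, and 3 lines of the table were emptied. Of 6021 protein-coding genes in the reference, 5113 are in the table. The mean count fell little with gene length (Spearman -0.141). GAL10 is not reported here.

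Library totals ran from 1162190 to 4167249 counts, with median counts per gene from 134 to 451. One count equals between 0.24 and 0.86 CPM of the library totals, and CPM of single genes were taken on totals times the TMM factors, and normalization factors ran from 0.9397 to 1.063. Of the 5219 genes, 33 fell below a mean count of 10 and were not tested, 15 of them on the W strand of chromosome XI from MTC2 to the right end, where a shift between strands was seen in the values and its starting position chosen by eye. Genes there were kept and a fit without them was added.

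Differential transcription was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling) in R 4.3.3, with condition and genotype as additive terms over all 6 libraries, which leaves 2 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 over the 5186 genes tested. The common dispersion was 0.00979 with 13 prior degrees of freedom. Such a fit tests a difference shared by the conditions, or a change shared by the strains, and says nothing on a single condition. The condition pairs and the difference in response have 1 library per group, so they carry no p, and genes were counted at 2-fold on log2 CPM with a prior count of 2. Exact 95% binomial intervals on counts were given for pairs, with a floor of 3 counts where a library held 0.

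In all, 30 gene lists were fixed from general knowledge before the data were examined, as were the comparisons, the tests, the naming rule and the first set of alternatives. Lists with 4 or more measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over 28 lists, and their medians were placed among 10000 random lists matched in 10 bins of level. The pattern that collects ribosomal protein genes at first also took RPP1 and was corrected after values were seen. Named genes were SPP1, the 10 highest and 10 lowest by mean genotype difference among genes with the same sign in all conditions, the 10 highest and 10 lowest by mean change at each time among genes with the same sign in both strains, and the 5 highest and 5 lowest differences in response at each time. Every Gal4 target, every COMPASS subunit and up to 4 members with the largest mean difference of each described list were added, and loci absent from the reference table were left out. Genes named outside this rule, namely the neighbours of SPP1, list members named because they passed or missed a test, TIP1, HPF1, MTC2 and RPL15B, were chosen after their values were seen.

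The fit was tested on data simulated with a single dispersion, with 50 genes changed per fold among 5186, equally in each affected library. It recovered 50% of genes at 1.5-fold and 100% at 2-fold for genotype, 32% and 94% for 15 min, and 52% and 98% for 60 min, and called 5, 4 and 7 unchanged genes. The alternatives chosen first were the prior count, the filter, the scaling between libraries (library medians, quantiles, RLE factors, library totals), limma with trend and robust options, DESeq2 1.42.0, the thresholds, and fits without each condition. Fits without the uncertain part of chromosome XI, and libraries thinned to a total of 1162030, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.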

Results

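Nascent transcription was measured by NET-seq (native elongating transcript sequencing), in which the RNA that co-purifies with RNA polymerase II is sequenced, here through a FLAG tag on the polymerase subunit Rpb3. The strains were budding yeast BY4741, either wild type or lacking SPP1, which encodes a PHD-finger subunit of COMPASS, the complex that methylates histone H3 on lysine 4. Each strain was sampled in glucose medium and at 15 and 60 min after transfer to galactose medium, which gives 6 libraries with 1 library per strain and condition and no replicates. Total counts over genes were 2528759 in glucose, 1270361 at 15 min and 1459874 at 60 min for the wild type, and 4167249, 1681514 and 1162190 for the deletion. The 10 most counted genes took between 4.34% and 6.26% of a library. Of 5219 genes in the table, 5186 reached a mean count of 10 and were tested. Genes on chromosome XI from MTC2 to the right end carry a limit of the counting. There, the median level of W-strand genes minus that of C-strand genes was -1.59 log2 units, and values of the 147 tested genes of this region are uncertain.

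**Figure D1:**
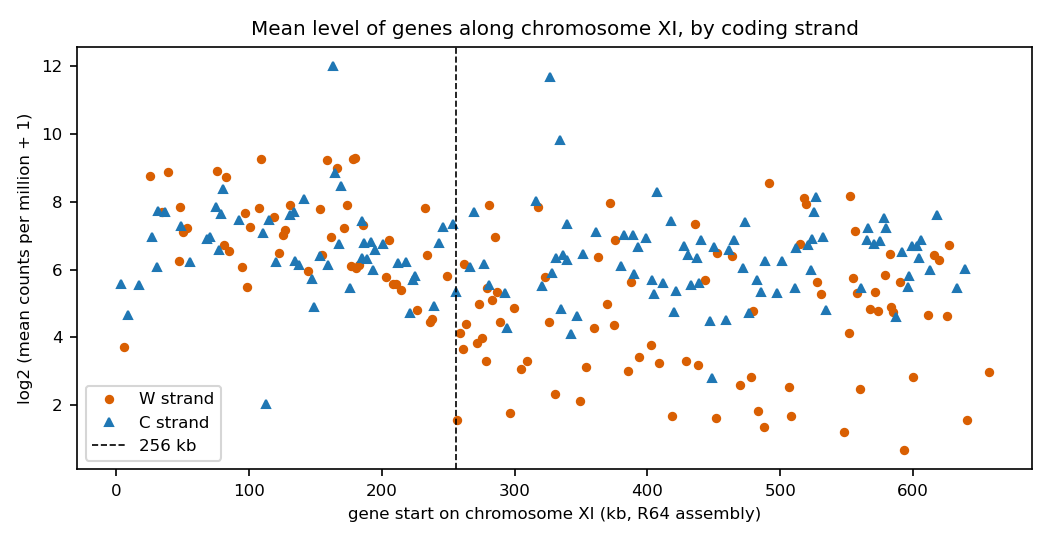
Mean level (vertical axis, log2 of mean CPM plus 1) of each gene along chromosome XI (horizontal axis, gene start in kb), 1 point per gene, with circles for the W strand and triangles for the C strand. Right of the dashed line, which stands at MTC2, many W-strand genes lie below the C-strand genes, a median log2 difference of -1.59.

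SPP1 itself (YPL138C, chromosome XVI, 291366 to 292427) checked the strain labels. The wild-type libraries held 324, 69 and 131 counts of SPP1 in glucose and at 15 and 60 min, and the deletion libraries held 1, 0 and 0. In glucose the wild-type level was 515-fold that of the deletion (exact 95% counting interval 91.8 to 20400). At 15 and 60 min it was at least 29.8-fold and at least 34.3-fold higher, against a floor of 3 counts per library; such intervals and floors cover counting error only. Among the nearest measured neighbours, FRK1 was lower in the deletion (log2 -0.58, Benjamini-Hochberg adjusted p = 0.0446, edgeR's quasi-likelihood test), while UME1 (log2 -0.56, adjusted p = 0.0674) and MKK2, GIP3, ISU1 and ODC1 did not pass the same test.

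The first comparison asked which genes are transcribed differently in the SPP1 deletion strain across all 3 conditions. Genes of ergosterol synthesis, which makes the main membrane sterol of yeast, and the cell-wall mannoprotein genes TIR1 and TIR3 were among the most strongly raised in the deletion. TIP1, of the same family, fell. Genes of the mating response of a cells were among those lowered. TIR1 (YER011W, chromosome V, 175248 to 176012), a cell-wall mannoprotein gene known from cold and anaerobic growth, went from 94, 12 and 9 counts in the wild type to 3892, 491 and 122 in the deletion. Its log2 difference was 4.68 ± 0.17 (Benjamini-Hochberg adjusted p = 9.86e-11, edgeR's quasi-likelihood test). Here and below, the value after ± is the size of the log2 value divided by the square root of the test's F. It stands in for a standard error and is only rough at low counts. TIR3, a relative of TIR1, was higher by 2.13 ± 0.28 (adjusted p = 4.86e-04, same edgeR test). Reads that the similar members of the TIR family share could not be separated here. TIP1 fell, from 807, 253 and 1060 counts to 403, 214 and 519 (adjusted p = 4.21e-03, same edgeR test), the mannoprotein gene HPF1 rose (1.25, adjusted p = 0.0143), and TIR2 (0.62, adjusted p = 0.347) and TIR4 (0.36, adjusted p = 0.657) did not pass it.

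Of 23 measured ergosterol genes, 15 rose in the deletion over all genes tested and 18 when adjusted over the list alone, and none fell. The sterol C-5 desaturase gene ERG3 (YLR056W, chromosome XII, 253861 to 254958) was higher by 2.40 ± 0.29 and the C-4 methyl oxidase gene ERG25 (YGR060W, chromosome VII, 610564 to 611493) by 2.16 ± 0.17, with edgeR Benjamini-Hochberg adjusted p of 3.00e-04 and 3.51e-06. ERG28, which encodes a scaffold of the C-4 demethylation enzymes, was higher by 1.47 ± 0.20 (adjusted p = 6.73e-04) and ERG5, the C-22 desaturase gene, by 1.34 ± 0.26 (adjusted p = 0.0133) in the same edgeR test. The 8 members that did not pass were ERG8, ERG10, ERG12, ERG20, ERG27, HMG1, HMG2 and IDI1. The list's median difference was 1.11 in glucose, 0.993 at 15 min and 0.466 at 60 min, and 21, 16 and 18 of its 23 members had a counting interval above 0 in these conditions. Its mean-over-conditions median of 0.896 lay at the 100 percentile of 10000 random lists of matched level. The camera set test gave an adjusted p of 7.04e-47 with the preset correlation, and adjusted p = 0.292 with an estimated correlation. Here and below, the estimated correlation rests on the 2 residual degrees of freedom of the fit.

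**Figure D2:**
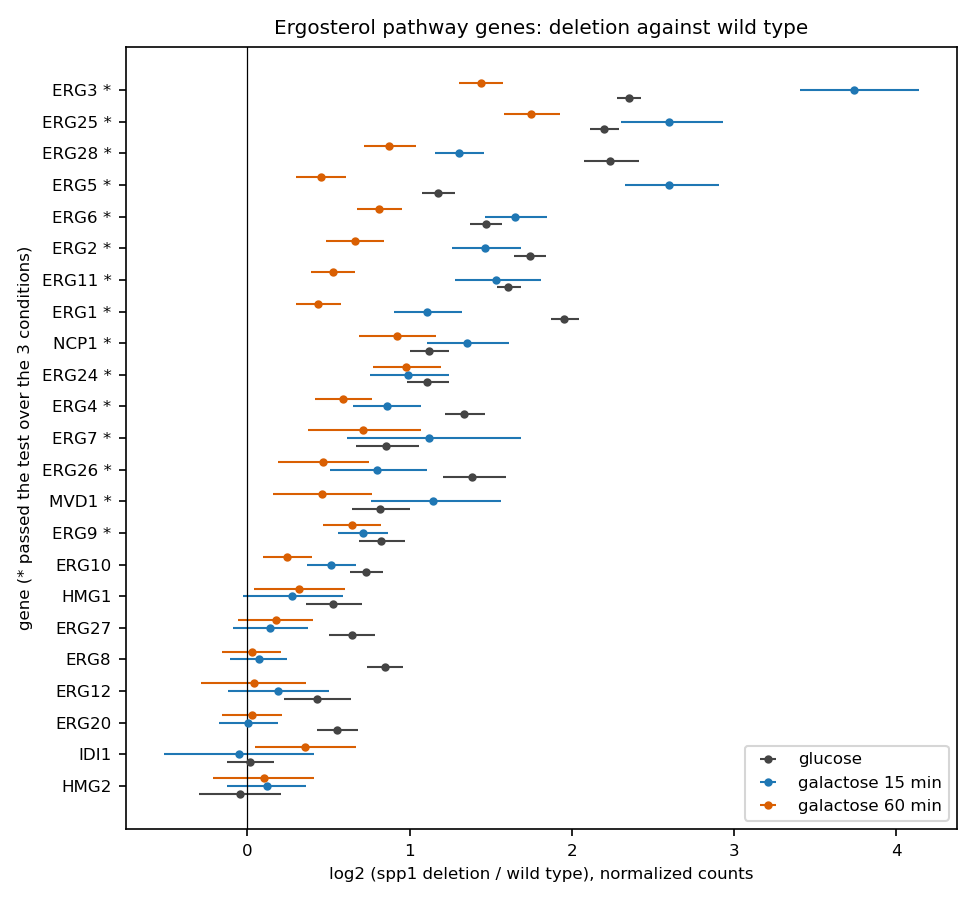
Log2 ratio of deletion to wild type (horizontal axis) for each of the 23 measured ergosterol genes (vertical axis), with 1 point per condition, bars for the exact 95% counting interval and stars on genes that passed the test. ERG3 and ERG25 lead by their mean over the conditions, and the list median falls from 1.11 in glucose to 0.466 at 60 min.

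Other raised genes were ATF2, which encodes an acetyltransferase that acts on alcohols and steroids (1.81 ± 0.16, adjusted p = 9.74e-06), CYB5, which encodes cytochrome b5 (1.65 ± 0.14, adjusted p = 9.41e-06), and the peroxiredoxin gene TSA2 (1.82 ± 0.16, adjusted p = 9.74e-06), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CSS1 (2.28 ± 0.36, adjusted p = 2.24e-03) and YNR064C (1.71 ± 0.33, adjusted p = 0.0113) also rose in that edgeR test, from low counts of 14, 3 and 2 and of 8, 10 and 7 in the wild type. Of 4 measured hexose transporter genes, HXT3 (0.86, adjusted p = 0.0106) and HXT2 (0.68, adjusted p = 0.0190) rose in the same edgeR test, over all genes and adjusted over the list alone. The camera adjusted p of that list was 1.40e-04, and adjusted p = 0.292 with an estimated correlation. Among 6 measured adhesin and mannoprotein genes, TIR1 and TIR3 rose and AGA1 fell, over all genes and adjusted over the list alone. The camera adjusted p of 1.97e-08 (adjusted p = 0.292 with an estimated correlation) came with TIR1 as a member. The median of this list was 0.769 in glucose, 0.202 at 15 min and 0.0888 at 60 min. These lay at the 100, 81.66 and 66.14 percentiles of random lists.

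Genes of the mating response were lower in the deletion. Of 7 measured MATa and pheromone response genes, 4 fell over all genes tested and all 7 fell when adjusted over the list alone. AGA1, which encodes the anchor subunit of a-agglutinin, fell by 1.34 ± 0.17 on the log2 scale and SST2, which encodes the GTPase-activating protein of the pheromone pathway, fell by 1.18 ± 0.14, with edgeR Benjamini-Hochberg adjusted p of 3.91e-04 and 1.98e-04. The a-factor gene MFA1 (log2 -0.72, adjusted p = 0.0190) and the a-agglutinin gene AGA2 (log2 -0.65, adjusted p = 0.0161) also fell in the same edgeR test, and MFA2, STE2 and KAR4 did not pass it over all genes. The median of the list was -0.583 in glucose, -0.471 at 15 min and -0.877 at 60 min. Its camera adjusted p was 7.48e-15, and adjusted p = 0.292 with an estimated correlation. Outside this list, ELO1, a fatty acid elongase gene, had the largest fall after SPP1, by 1.49 ± 0.20 (edgeR Benjamini-Hochberg adjusted p = 5.14e-04). YER053C-A (log2 -1.20, adjusted p = 0.0115), YNL040W (log2 -1.03, adjusted p = 2.14e-03) and the DNA ligase IV gene DNL4 (log2 -1.20, adjusted p = 0.0494) fell too in the edgeR test, the last not when each library was centred on its median. RSB1 (log2 -0.99, adjusted p = 0.0619), AFB1 (log2 -1.19, adjusted p = 0.0503) and HIM1 (log2 -0.76, adjusted p = 0.450) ranked among the lowest but did not pass the edgeR test.

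In each of the remaining gene groups at most 2 members passed the test over all genes. Of 136 ribosomal protein genes 0 passed edgeR's test over all genes or adjusted over the list alone, and 0 in limma or DESeq2, with 22 at an unadjusted p under 0.05 in edgeR. Their median difference was -0.181, and -0.0245, -0.13 and -0.396 in glucose and at 15 and 60 min (camera adjusted p = 1.14e-06, and adjusted p = 0.954 with an estimated correlation). In the list of 25 cell cycle genes 1 fell, CDC6, a DNA replication licensing gene (log2 -0.75, edgeR Benjamini-Hochberg adjusted p = 7.77e-03), with 2 when adjusted over the list alone. Their median was -0.208 (camera adjusted p = 7.29e-05, and adjusted p = 0.480 with an estimated correlation). Among 7 measured COMPASS genes only SPP1 passed edgeR's test over all genes, with BRE2 higher as well when adjusted over the list alone, and the camera adjusted p of 8.30e-07 (adjusted p = 0.292 with an estimated correlation) came with the deleted gene as a member. The Hsf1 chaperone genes had a median of 0.134, with 1 of 24 raised over all genes and adjusted over the list alone, HSP26 (0.97 ± 0.16, edgeR Benjamini-Hochberg adjusted p = 2.77e-03). The Gcn4 amino acid genes had a median of 0.109, with ARG1 raised and ARG8 lowered among 43 (4 raised and 2 lowered when adjusted over the list alone), and the 33 proteasome genes a median of 0.0995 with 0 passing edgeR's, limma's or DESeq2's test and 0 at an unadjusted p under 0.05 in edgeR. In glucose and at 15 and 60 min, HSP26 differed by 0.03, 1.09 and 1.09, and ARG1 by 2.17, 0.41 and 0.71. The camera adjusted p of the Hsf1, Gcn4 and proteasome lists were 0.0344, 0.0394 and 0.0415, and with an estimated correlation the adjusted p = 0.954, 0.954 and 0.619. The other 18 of 28 lists large enough for camera did not pass it with either correlation, and their few called members were CIT3 (0.88) and MET13 (0.65), raised, and CYC1 (log2 -0.65) and COS10 (log2 -0.65), lowered. Of 2 lists too short for camera, the MATalpha-specific genes AFB1 and SAG1 (log2 -0.33) had a median of -0.602, with 0 called over all genes by edgeR, limma or DESeq2, 1 at an unadjusted p under 0.05 in edgeR and AFB1 lower when adjusted over the list alone. In the other, of loci deleted in BY4741, only HIS3 was measured (0.33, edgeR Benjamini-Hochberg adjusted p = 0.203 over all genes, called higher when adjusted over the list alone).

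Over all genes, 95 of 5186 (1.83%) differed with genotype, 57 higher and 38 lower in the deletion, and 33 of them by at least 2-fold. The 3 conditions of each strain stood in for replicates. The p-values therefore measure variation between conditions, not between isolates or cultures of a strain. A difference that these cultures carried for a reason other than SPP1 would pass as well. In 94 of the 95 the direction was the same in all 3 conditions, which the test for a shared difference largely selects for. The exception was YSR3, which lies in the uncertain part of chromosome XI. Among all genes tested 36% had the same sign in all 3 conditions, against 25% for independent signs. In the self-test on simulated counts of the 5186 genes, this test recovered 50% of genes changed 1.5-fold and 100% of those changed 2-fold. The simulated genes shared a single dispersion and had the same fold in all 3 conditions. These shares therefore do not hold for differences that vary between conditions, and AFB1, at log2 -1.19, did not pass. The test rests on 2 residual degrees of freedom and on a difference shared by conditions: without the glucose libraries 62 genes passed, 195 without the 15 min and 172 without the 60 min libraries, and DESeq2 called 50 (38 higher, 12 lower) and limma 70, each without some of the list members named above. With library totals as the only scaling, 58 genes were higher and 81 lower.

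In single conditions, with no replicate check and no test, the deletion differed from the wild type by at least 2-fold in 63 genes in glucose (44 higher, 19 lower), 117 at 15 min (82 higher, 35 lower) and 88 at 60 min (62 higher, 26 lower). In 9 genes, among them TIR1, TIR3, ERG3, ERG25, ATF2 and CYB5, the deletion was at least 2-fold higher in each condition, and in 2 genes, SPP1 and AGA1, at least 2-fold lower. Across genes, which are not independent replicates, the differences correlated with a Pearson r of 0.392 between glucose and 15 min, 0.36 between glucose and 60 min and 0.288 between 15 and 60 min. ERG3 was higher by 2.35 in glucose (exact 95% counting interval 2.28 to 2.43), 3.74 at 15 min (3.41 to 4.14) and 1.44 at 60 min (1.31 to 1.58). The number of genes past 2-fold fell to 39, 34 and 36 with a 10 times larger prior count.

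The next comparison asked what the transfer from glucose to galactose changed in both strains. Stress, storage carbohydrate and respiratory genes rose by 15 min, while genes for making ribosomes fell. Counts in the lists below were the same adjusted over the list alone unless stated. All 18 measured Msn2/4 general stress genes rose, with a median log2 change of 4.26. HSP12, which encodes a small membrane-associated stress protein, went from 15 to 6280 counts in the wild type and from 27 to 8240 in the deletion (9.71 ± 0.38, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.05e-12), and DDR2 rose by 7.78 ± 0.28 (adjusted p = 4.16e-12, same edgeR test). Of 17 trehalose and glycogen genes 16 rose and 1, GLG1, which lies in the uncertain part of chromosome XI, fell, with a median of 3.97. The glycogen branching enzyme gene GLC3 rose by 7.49 ± 0.27 and the glycogen synthase gene GSY1 by 7.24 ± 0.26, with edgeR adjusted p of 4.23e-12 and 3.76e-12. Of 14 glucose-repressed carbon genes 13 rose with a median of 3.04, led by the hexokinase gene HXK1 (7.49 ± 0.32) and the glucokinase gene GLK1 (6.62 ± 0.28), which shares its span with another gene. All 32 respiratory chain genes and 18 of 19 tricarboxylic acid cycle genes rose, with medians of 2.43 and 2.19. Other strong rises were RGI1 (8.17), TMA10 (7.61), BDH2 (7.48), the phosphoglucomutase gene PGM2 (7.35) and DCS2 (7.31).

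All 79 measured ribosome biogenesis genes fell at 15 min, with a median log2 change of -4.52, as did all 18 genes for subunits of RNA polymerases I and III (median -3.66) and 135 of 136 ribosomal protein genes (median -2.53). The exception was RPL15B at 0.09. NSR1, which encodes a nucleolar protein of rRNA processing, went from 2778 to 10 counts in the wild type and from 4807 to 15 in the deletion (log2 -6.98 ± 0.25, edgeR Benjamini-Hochberg adjusted p = 3.76e-12). MAK16, needed for the large ribosomal subunit, went from 1150 to 8 and from 1658 to 4 counts. RPA49, which encodes a subunit of RNA polymerase I, went from 780 to 2 and from 1265 to 7, SPB1 from 794 to 2 and from 1306 to 7, RCL1 from 723 to 2 and from 1106 to 4, and RSA4 from 534 to 0 and from 981 to 5. NOG2, which shares its span with another gene, went from 2080 to 4 and from 3328 to 9. AIR1, NRP1 and the repressor gene TOD6 ended at 5 counts or fewer in both strains, from at least 572. Of 12 RNA polymerase II subunit genes 9 fell, with a median of -0.6. The camera adjusted p of the stress, storage, glucose-repressed, respiratory, tricarboxylic acid cycle, ribosome biogenesis, ribosomal protein, polymerase I and III and polymerase II lists were 3.73e-17, 1.02e-14, 1.08e-07, 6.43e-13, 5.12e-07, 3.93e-48, 7.62e-28, 1.02e-14 and 0.0364 with the preset correlation. In the same order, adjusted p = 0.374, 0.288, 0.288, 0.569, 0.590, 0.288, 0.524, 0.288 and 0.456 with an estimated correlation. In all, 3900 genes changed at 15 min, 1926 up and 1974 down, and 2344 of them by at least 2-fold, in the same edgeR test. TMM scaling assumes that most genes do not change, yet 75.2% of genes passed at 15 min and 66.2% at 60 min. Rises and falls are thus relative to the rest of each library. A change of total transcription could not be seen, and the near-even split depends on the scaling. The galactose cultures were also centrifuged and resuspended, per the labels' protocols, and the glucose cultures are not described so, which leaves handling and medium together in every change against glucose.

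At 60 min the same gene groups were changed, mostly by less. The glucose transporter genes HXT1 and HXT3 and the adenine deaminase gene AAH1 joined the most strongly lowered. The Msn2/4 genes had a median log2 change of 3.53, with all 18 raised, and HSP12 stood at 9.44 ± 0.38 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.92e-11). Trehalose and glycogen genes had a median of 2.87 (15 raised, and 1 lowered, again GLG1 of the uncertain part of chromosome XI), glucose-repressed genes 2.92 (13 of 14 raised), respiratory chain genes 2.14 (all 32 raised) and tricarboxylic acid cycle genes 1.84 (18 of 19 raised). TMA10 (7.42), DDR2 (7.53), HXK1 (6.87), GAC1, a regulatory subunit gene of the phosphatase of glycogen synthase (6.85), SPG4 (6.83), LEE1 (6.48), YMR206W (6.46) and the mitochondrial pyruvate carrier gene MPC3 (6.41) rose most among genes ranked by their mean change. The ribosome biogenesis median was -2.71 (all 79 lowered), that of polymerase I and III subunits -2.09 (all 18 lowered) and that of ribosomal protein genes -1.68 (135 of 136 lowered). Of 12 RNA polymerase II subunit genes 7 fell, and this list did not pass camera at 60 min.

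Among the strongest falls at 60 min were single genes of different roles. The low-affinity glucose transporter gene HXT1 went from 1003 to 6 counts in the wild type and from 1535 to 14 in the deletion (log2 -5.71 ± 0.26), and HXT3 from 1312 to 12 and from 3779 to 34 (-5.40 ± 0.24), with edgeR Benjamini-Hochberg adjusted p of 6.00e-11 and 6.24e-11. AAH1 went from 804 to 2 and from 1054 to 3 counts, and the RNA helicase gene DBP2 from 2471 to 17 and from 4326 to 12 (log2 -6.58 ± 0.24, edgeR adjusted p = 2.14e-11). GFD2 went from 550 to 2 and from 932 to 13, TOD6 from 572 to 9 and from 926 to 9, and NSR1 (-4.83), RFU1 (-4.76) and the CTP synthase gene URA7 (-4.66) fell as well. In all, 3433 genes changed at 60 min, 1675 up and 1758 down, and 1727 by at least 2-fold, again relative to the scaling of the libraries. The camera adjusted p of the stress, storage, glucose-repressed, respiratory, tricarboxylic acid cycle, ribosome biogenesis, ribosomal protein and polymerase I and III lists were 3.29e-18, 3.27e-14, 5.28e-12, 2.17e-15, 1.39e-09, 7.94e-48, 7.17e-23 and 4.19e-12. With an estimated correlation, adjusted p = 0.426, 0.269, 0.269, 0.504, 0.504, 0.269, 0.504 and 0.426.

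At 15 min most cell cycle genes and amino acid synthesis genes were lowered, and most chaperone genes raised. Of 25 cell cycle genes, which include cyclins and G1/S genes, 23 fell and 1 rose at 15 min, among them the ribonucleotide reductase gene RNR1 (log2 -4.63 ± 0.27) and the G1 cyclin gene CLN2 (-3.97 ± 0.22), and 11 fell and 4 rose at 60 min. The list medians were -1.70 and -0.503. Of 43 Gcn4 amino acid genes 28 fell and 4 rose at 15 min, led by LEU9 (-4.59 ± 0.20), which acts in leucine synthesis, and LYS4 (-4.48 ± 0.18), which acts in lysine synthesis, and 29 fell and 2 rose at 60 min, with medians of -0.88 and -0.811. Of 24 Hsf1 chaperone genes 15 rose and 5 fell at 15 min (16 and 5 adjusted over the list alone), led by HSP42 (6.04 ± 0.25) and HSP26 (5.97 ± 0.23), and 11 rose and 7 fell at 60 min. The camera adjusted p at 15 min of the cell cycle, Gcn4 and Hsf1 lists were 1.65e-03, 9.22e-04 and 3.09e-03, and with an estimated correlation adjusted p = 0.347, 0.590 and 0.668. At 60 min only the Gcn4 list of these passed camera (adjusted p = 4.68e-04, and adjusted p = 0.504 with an estimated correlation).

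**Figure D3:**
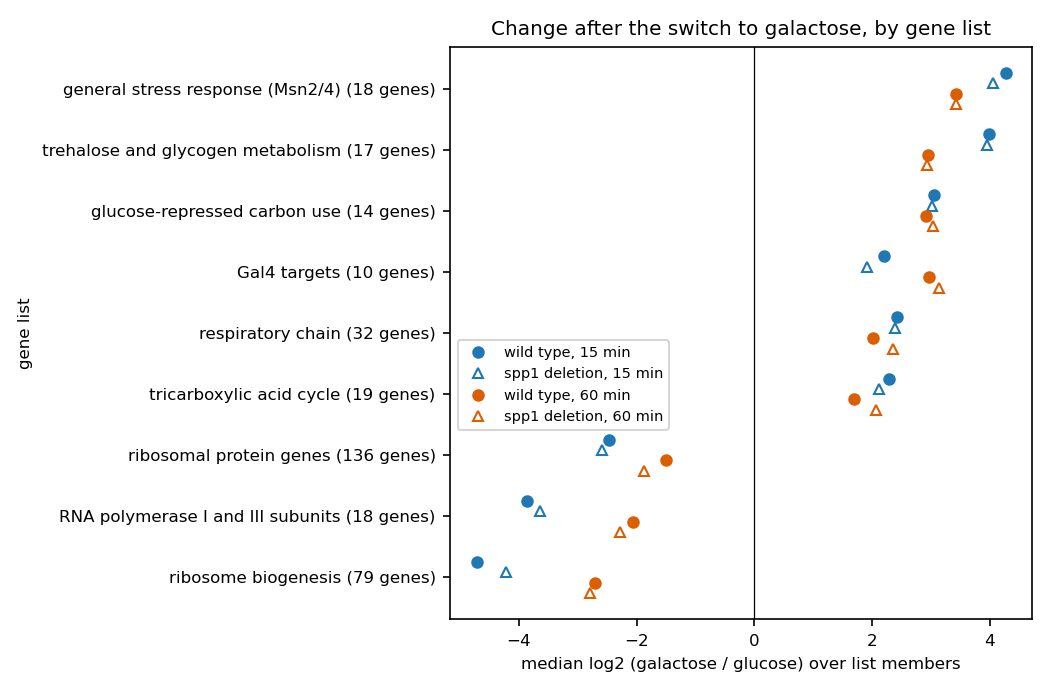
Median log2 ratio of galactose to glucose (horizontal axis) over the members of 9 gene lists (vertical axis), 1 library pair per point, with filled circles for the wild type and open triangles for the deletion. Stress genes (4.26 over both strains at 15 min) and ribosome biogenesis genes (-4.52) mark the ends at 15 min, and both lie closer to 0 at 60 min.

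The time points shared most changes. Of the genes called at 15 and at 60 min, 1517 were higher at both and 1595 lower at both, where independent lists would share 622.1 and 669.2. Across genes the log2 changes at the 2 times had a Pearson r of 0.933 and a covariance of 2.43, against 0.391 and 0.0141 in 20 simulations with no effect and the same glucose libraries, and 88.8% of genes moved the same way against 64.1%. The simulated changes shared the glucose libraries as well, and in them the covariance reached at most 0.0154 and 0 genes were called at both times, against 3151. Sharing at the fitted dispersion therefore gave little of the covariance. An error of the glucose libraries beyond that dispersion was not simulated. For the 1926 genes raised at 15 min, the median change was 1.17 at 15 min and 0.814 at 60 min in the wild type, and 1.07 and 0.831 in the deletion. For the 1974 lowered genes it was -1.41 and -0.85 in the wild type and -1.29 and -0.952 in the deletion, and these genes were chosen on the 15 min libraries.

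Genes known as targets of the activator Gal4 were followed one by one, though their dependence on Gal4 was not measured here. Most rose, the structural GAL genes from low counts. Of 10 measured targets, 6 rose and 2 fell at 15 min (7 and 2 adjusted over the list alone), and 7 rose and 1 fell at 60 min, with median log2 changes of 2.06 and 3.04. GAL1, the galactokinase gene (chromosome II, 279021 to 280607, sharing its span with another gene), held 25, 17 and 76 counts in the wild type and 23, 19 and 49 in the deletion. Its log2 change was 0.80 at 15 min (edgeR Benjamini-Hochberg adjusted p = 0.0559) and 2.56 ± 0.29 at 60 min (adjusted p = 1.01e-06). GAL7 rose by 1.89 and 2.77, the galactose permease gene GAL2 by 3.63 and 3.95, and the galactose sensor gene GAL3 by 2.46 and 4.10 at 15 and 60 min. PGM2 (7.35 and 5.70), MTH1 (5.32 and 4.98) and GCY1 (4.05 and 4.09) rose more at 15 min than these GAL genes, and GAL80, which encodes the repressor of Gal4, did not pass at either time (0.18 and 0.20). The uracil permease gene FUR4 fell at both times (-3.58 and -0.63) and the cyclin gene PCL10 at 15 min (-0.99, and -0.09 at 60 min). The camera adjusted p of the list was 7.77e-03 and 3.74e-06, and with an estimated correlation adjusted p = 0.456 and adjusted p = 0.426. With genotype 0 of the 10 passed edgeR's, limma's or DESeq2's test, with 3 at an unadjusted p under 0.05 in edgeR and a list median of -0.0545; at 60 min GAL1 stood at 49.0 CPM (on library totals times their TMM factors) in the wild type and 40.2 in the deletion.

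**Figure D4:**
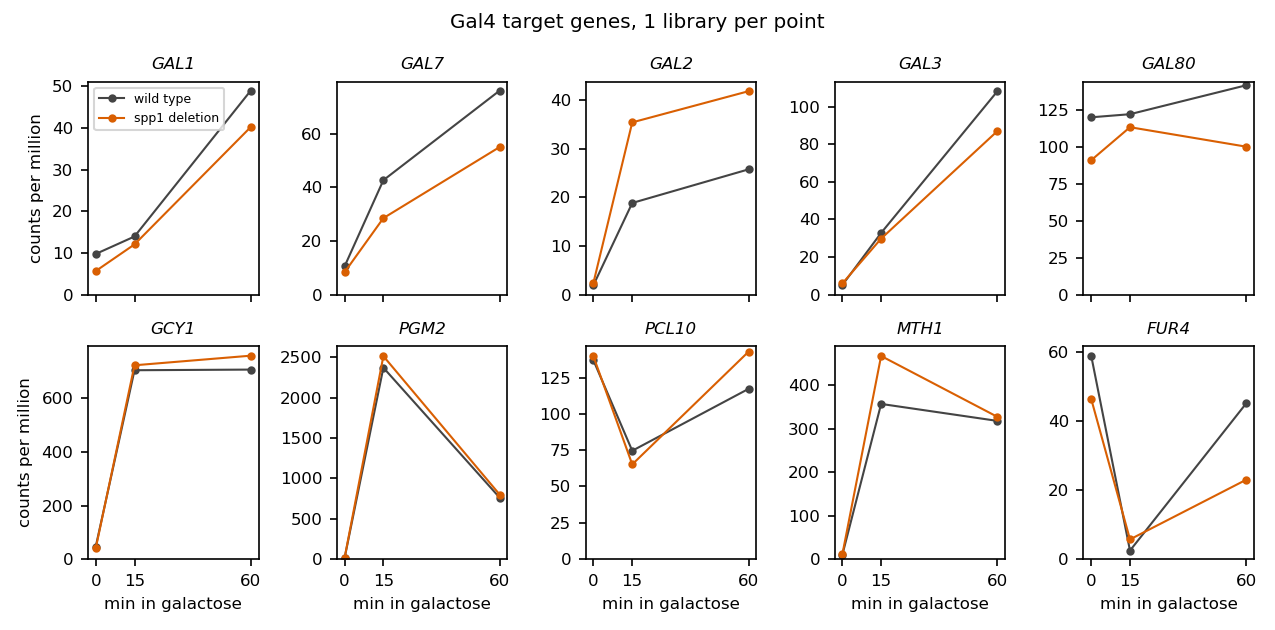
CPM after TMM scaling (vertical axes, linear, 1 scale per gene) of the 10 Gal4 targets against min in galactose (horizontal axes), with grey for the wild type, orange for the deletion and 1 library per point. GAL1 climbs mainly after 15 min, to 49.0 and 40.2 CPM, while PGM2, MTH1 and GCY1 reach high levels by 15 min in both strains.

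Genes for the other COMPASS subunits were followed beside SPP1. SET1, which encodes its methyltransferase, fell by 2.07 at 15 min and fell by 0.98 at 60 min, and BRE2 fell by 1.28 and fell by 0.86, in both strains together (edgeR Benjamini-Hochberg adjusted p of 1.86e-07 and 1.76e-04 for SET1, and 5.83e-05 and 1.66e-03 for BRE2). SDC1 passed only at 15 min (-0.58 and -0.32), and SWD1, SWD3 and SHG1 at neither time. None of these 6 differed with genotype in edgeR's test over all genes, and the values nearest to a difference were BRE2 at 0.51 ± 0.17 (adjusted p = 0.188) and SWD1 at -0.26 ± 0.12 (adjusted p = 0.371).

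Whether the response to galactose itself differs without SPP1 could be described but not tested, with 1 library per strain and condition. Single genes with the largest differences had different roles, and some gene lists lay at the ends of the random lists. The change differed between strains by at least 2-fold in 129 genes at 15 min (84 higher in the deletion, 45 lower) and 125 at 60 min (87 higher, 38 lower), and the 2 strains' changes correlated across genes with a Pearson r of 0.978 and 0.96. At 60 min the largest differences of deletion minus wild type were 3.29 for YDR042C, 2.27 for GFD2, 2.05 for the weak-acid transporter gene PDR12, 2.02 for RSB1 and 1.94 for BIO5, and on the lower side -2.19 for the phosphate transporter gene PHO89, -2.07 for YSR3, -1.98 for HIM1, -1.71 for TIR3 and -1.69 for AMS1. YDR042C and GFD2 rest on 2 counts each in the wild type at 60 min against 13 in the deletion. PHO89 held 276 and 977 counts in the wild type in glucose and at 60 min, against 2104 and 803 in the deletion. At 15 min OYE3 (2.17), LPX2 (2.00), RSA4 (1.87) and NOC3 (1.84) were highest, and YSR3 (-3.61), the aquaporin gene AQY2 (-2.06), TIS11 (-1.81), YOX1 (-1.79) and the arginine synthesis gene ARG1 (-1.76) lowest. YSR3 and LPX2 lie in the uncertain part of chromosome XI, AQY2 shares its span with another gene, and RSA4 and NOC3 rest on 0 and 2 wild-type counts at 15 min. Among the fixed lists, the median difference in response at 60 min lay at the 100 percentile of random lists for tricarboxylic acid cycle (0.335) and respiratory chain (0.27) genes. It lay at the 0 percentile for glycolysis (-0.667), phosphate (-0.606), ergosterol (-0.486), ribosomal protein (-0.361) and Gcn4 amino acid (-0.28) genes. At 15 min it did so for Hsf1 chaperones (0.446, 100 percentile) and the iron regulon (-0.5, 0 percentile), and these percentiles describe these libraries only. With a 10 times larger prior count the numbers past 2-fold were 34 at 15 min and 64 at 60 min.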

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

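A gene was singled out here when its counting interval lay above 0 in at least 1 of the conditions or strains and below 0 in another, and a gene list when its median lay in the top 2.5% of random lists in one condition and the bottom 2.5% in another. With 1 library per strain and condition these differences were not tested. The gap is that between the highest and the lowest value, and all values are log2 units.

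Among stress and storage genes, the deletion minus wild type difference of DDR2 was 0.25 at 60 min and -0.12 at 15 min, a gap of 0.374, and that of BDH2 was 0.48 and -0.43, a gap of 0.9079. For DCS2 it was 0.36 in glucose and -0.16 at 15 min (gap 0.5264), and for GSY1 0.35 in glucose and -0.29 at 60 min (gap 0.6418). The glucose intervals of both include 0 (-0.3987 to 1.248 and -0.3031 to 1.103), and the intervals above 0 were those of DCS2 at 60 min (0.02793 to 0.3074) and GSY1 at 15 min (0.08926 to 0.2484).

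Gaps of more than 1.5 came from 5 genes, all of them named for their large differences in response, so that the gaps restate that choice. YDR042C differed by 2.36 at 60 min and -0.93 in glucose (gap 3.286), the oxidoreductase gene OYE3 by 1.31 at 15 min and -0.87 in glucose (gap 2.172), AQY2 by 0.55 in glucose and -1.51 at 15 min (gap 2.06) and TIS11, which acts in mRNA decay under low iron, by 1.23 in glucose and -0.58 at 15 min (gap 1.809). LPX2, a peroxisomal lipase gene in the uncertain part of chromosome XI, changed at 15 min by -1.19 in the wild type and 0.81 in the deletion (gap 2.003). Some of these rest on few counts in the wild type and the deletion: 2 and 13 for YDR042C at 60 min, and 11 and 4 for AQY2 and 6 and 25 for LPX2 at 15 min.

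Gene lists showed smaller gaps. Ribosome biogenesis had a median genotype difference of 0.191 at 15 min and -0.14 at 60 min (gap 0.331), the respiratory chain 0.175 at 60 min and -0.245 at 15 min (gap 0.42), and Hsf1 chaperones 0.327 at 15 min and -0.0637 in glucose (gap 0.391). Methionine and sulfur genes stood at 0.262 at 15 min and -0.417 at 60 min (gap 0.679), the phosphate regulon at 0.348 in glucose and -0.208 at 60 min (gap 0.556), and the iron regulon at 0.222 in glucose and -0.278 at 15 min (gap 0.5).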

How the results depend on the processing

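No called list median and no called value of a named gene changed sign under the alternatives run for them, but the larger side of a count did change. Genotype went from 57 higher and 38 lower to 58 and 81 with library totals and 84 and 91 at an adjusted p of 0.1. The 60 min count went from 1675 and 1758 to 1863 and 1613 with library totals, and the 15 min count from 1926 and 1974 to 1990 and 1837 with quantiles. The glucose ratio went from 44 and 19 to 125 and 137 at 1.5-fold. Library totals and quantiles moved the log2 median of all genes to the side that grew. With library totals it went from 0.00559 to -0.0288 for genotype and from -0.02 to 0.0622 at 60 min. With quantiles it went from -0.0133 to 0.0544 at 15 min. The cause of the changes with the thresholds was not tested. The genotype count of 95 moved to 51 with a filter at the 25th percentile of the gene means, 50 with DESeq2 and 175 at an adjusted p of 0.1, and to 62 without glucose, 195 without 15 min and 172 without 60 min libraries; the first and the last 3 also change the genes or libraries in the fit, and otherwise the cause was not tested. Other settings kept it between 70 (limma) and 139 (library totals). Counts at 2-fold fell with a 10 times larger prior count to 39 in glucose, 34 at 15 min and 36 at 60 min, and for the difference in response to 34 and 64, since the prior pulls low counts together. With a 1.5-fold threshold they were 262, 433 and 465, and 542 and 605, since the threshold is lower. The galactose counts stayed between 3031 and 4108 at 15 min and 2732 and 3718 at 60 min. Of 33 camera calls, all 33 were lost with an estimated correlation, which rests on the 2 residual degrees of freedom of the fit. Its lowest camera adjusted p was 0.269, at 60 min. Lists with a negative estimated correlation lost their call too, as COMPASS (-0.149) and hexose transporters (-0.236) did for genotype. With so few degrees of freedom, a lost call is little evidence that a list did not change. Calls of named genes were redone one by one only with median centring, where DNL4 lost its call. In the other tools' list counts for genotype, DESeq2 called neither ARG1, ARG8, CDC6 nor COS10 and 3 of 4 pheromone genes, limma called neither HSP26 nor CIT3 and 1 of 2 hexose transporters, and ergosterol genes were 11 in limma and 13 in DESeq2 against 15. For galactose several lists also lost calls, among them FUR4 at 60 min in both tools and GLG1 at 15 min in DESeq2. The larger prior count moved 61 of 97 named values by more than the limit set for them. That limit was the ± value of the fit as defined above or, for differences in response, the counting interval. The added fit without the uncertain part of chromosome XI called 81 genes for genotype. Thinned libraries, also added after seeing the data, gave 89, 109 and 89 genes at 2-fold in glucose and at 15 and 60 min, against 63, 117 and 88. In glucose 49 of the thinned genes were higher and 40 lower, against 44 and 19. Depth limits genes with a few counts per library, in which a 2-fold difference rests on single reads.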

Other observations

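Several further gene groups moved after the switch to galactose without passing camera as lists. Of 10 histone genes 8 rose at 15 min, among them HHT2 (1.05 ± 0.17) and HHF1 (0.83 ± 0.14), while at 60 min 5 fell and 1 rose, with HTB2 at -1.60 ± 0.17 and HTA2 at -1.55 ± 0.18. Of 16 iron regulon genes 11 rose and 1 fell at 15 min and 4 rose and 2 fell at 60 min. The cell-wall siderophore genes FIT3 (3.65 ± 0.16 and 3.36 ± 0.16) and FIT2 (3.62 ± 0.24 and 2.33 ± 0.24) led. Of 33 proteasome genes 29 rose at 15 min (30 adjusted over the list alone) and 14 at 60 min (13 adjusted over the list alone).

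Hexose transporter and phosphate genes went both ways. The hexose transporter genes HXT4 (4.94 ± 0.20 and 2.12 ± 0.25) and HXT2 (2.71 ± 0.18 and 1.49 ± 0.18) rose at 15 and 60 min, and HXT1 and HXT3 fell at both. Of 13 phosphate regulon genes 8 fell and 1 rose at 15 min, with the phosphate transporter gene PHO84 at -3.27 ± 0.25, and 4 rose and 1 fell at 60 min, with GPP2 at 1.78 ± 0.17. Of 7 pheromone response genes all 7 fell at 15 min, and of 23 ergosterol genes 14 fell and 3 rose, with ERG11 at -2.52 ± 0.25.

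For the genotype count, the 6 libraries can be split into 3 and 3 in 10 ways, each fitted with condition as a block, a test written before its result was seen. The real split called 95 genes and the highest other split 1, so that 1 of 10 splits reached the real count. The 10 splits are too few for a share under 0.05. Some of the other splits also put both libraries of a condition on the same side. In all of them much of the real genotype difference goes into the residual. Low counts in the other splits were thus built in, and no conclusion is drawn from them.

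For the raised ergosterol genes, the tests of low oxygen and of scaling were written before their results were seen, and that of Upc2 after. Both gene lists were put together after the ergosterol result was seen. Low oxygen in the deletion cultures would raise hypoxic genes repressed by Rox1, but 11 such genes had a median difference of 0.0442 (resampling range -0.0925 to 0.31). Over all genes 0 of them were called higher and 1 lower, and 1 higher and 1 lower when adjusted over the list alone. The range passes the limit of 0.25 set for this test, and TIR1 and TIR3 are not in that list, so low oxygen stays open. For scaling between libraries, the lowest list median over 5 scalings was 0.861, so the rise did not depend on which of these was used. They moved the genotype median of all genes only between -0.0288 and 0.0159. They could therefore hardly have removed the rise, and the test does not bear on other scalings. A higher activity of the sterol regulator Upc2 stays open: 9 of its targets outside the pathway had a median of 1.06 (0.214 to 1.92) and 6 were called higher, but the list holds genes already called and decides nothing.

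For the low W-strand genes of chromosome XI, the tests were chosen after the result was seen. The W minus C difference was -1.59 there and between -0.478 and 0.386 elsewhere, a description only, since the start of the region was chosen by eye from this shift. Gene windows placed with coordinates of another assembly version stay open as an explanation and were not checked against any coordinates. Missing or unmappable DNA would lower both strands, yet C-strand genes in the first part exceeded those in the rest by only 0.33, against 2.31 for W-strand genes. No biological explanation was tested.

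For the 60 min libraries, the tests were also chosen after the result was seen. The genotype difference at 60 min correlated across genes with the wild-type change at 15 min, which shares no library with it (Pearson 0.225), and in the 2788 genes with at least 100 counts in each of the 4 libraries the Spearman was 0.359, which speaks against counting noise in low genes. At 15 min the genotype difference correlated with the wild-type change at 60 min at -0.175, and at -0.0924 (Spearman -0.103) in 2970 genes with such counts, and in glucose with the wild-type change from 15 to 60 min at -0.0115. An earlier stage of the response in this library, by harvest timing or slower adaptation, stays open, since the correlation restates the pattern seen and 1 library per strain and time is confounded with its harvest.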
